A study of Mus musculus with 5 samples.

How the data were processed

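RNA from aortic cells of 5 mice aged 26 weeks was sequenced, with 2 libraries labelled ApoE knockout and 3 labelled ApoE/Neil3 double knockout, each from a separate mouse per the series design. Per the labels' protocols, aortas were broken up, cells were selected with CD31 and CD90.1 magnetic beads, and RNA from spin columns went into libraries made with the NEBNext Ultra RNA kit. Which bead fraction was kept, the sex of the mice and the strand setting of the counting are not given in the sources used here.

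The deposited files hold estimated counts per RefSeq transcript, in the layout kallisto writes per the file headers. Per the submitters' processing notes, fastp 0.20.0, kallisto 0.46.0 and sleuth 0.30.0 were used with mouse build GRCm38.p6, with no role or order given for each tool. A further deposited table from the authors holds a normalized signal: tested on the file, each value is the sample's estimated count multiplied by 1 factor per sample (2.83, 1.27, 0.501, 0.809 and 0.686), and it keeps the transcripts with at least 5 estimated counts in 3 or more samples. That table served only as an alternative. Effective transcript lengths, deposited beside the estimated counts, entered only the alternatives that use TPM or length offsets.

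Transcripts were paired with genes through a RefSeq gene table of the same build, which also gave the coordinates. Of 121318 transcripts, 116643 (96.1%) matched 37833 genes. The transcripts that matched no gene held 4.11% and 3.40% of the counts in ApoE knockout replicates 1 and 2 and between 1.60% and 1.68% in the libraries labelled double knockout. They stayed out of the gene test. A ribosomal RNA precursor was the largest among them, with 0.798% to 3.04% of all counts. No mitochondrially encoded gene was measured. Estimated counts were summed per gene and rounded to whole numbers. Reads shared between near-identical genes (the alpha and beta globin genes, the Mup family, Rn7s1 and Rn7s2) are divided by estimation, so values of single members are uncertain. Overlapping and antisense genes may share reads too, since the strand setting is unknown.

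The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, its expression filter (12968 genes kept), a quasi-likelihood fit with robust shrinkage, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Normalised CPM values use TMM library sizes. Error is given as SD over 2 and 3 libraries, or as the standard error (SE) of the fitted log2 fold change. Where every library of a group is at 0, the mean of the other group is divided by 3 counts pooled over the group at 0. That is 0.993 CPM in the ApoE knockout and 0.243 CPM in the group labelled double knockout. The resulting lower bound of the fold holds for the mean only and leaves out the spread between libraries, so single libraries can lie lower. Floors, Poisson limits and intervals of count ratios cover counting error only, and no molecular identifiers are named in the labels. The interval for Neil3 comes from the edgeR fit, and those for lists are bootstraps over their genes, which treats the genes as independent.

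In advance, 33 gene lists were fixed, and 29 of them with at least 5 measured genes entered camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01. Camera compares a list with all other genes. An estimated correlation and fry were alternatives. Genes to be named were fixed by rule: Neil3 and Apoe; up to 12 genes per direction past the threshold with no overlap between groups, filled to 5 per direction by smallest unadjusted p among genes with a mean of at least 1 CPM, leaving out pseudogenes and unnamed predicted genes; up to 4 members of each called list and 2 of each other list described. One gene that this rule selects is not reported here. The 6 uncalled lists whose members are named, 4 further lists (chondrocyte, hepatocyte, marrow granulocyte, erythroid precursor) and the settings that thin reads to the smallest library total with haemoglobin included, leave out haemoglobin, Mup and structural RNA genes, or test lists on library totals were chosen after the data had been seen.

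The alternatives set before the data were examined were RLE normalization, library totals, no expression filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, length offsets, log2(TPM + 0.5) and log2 of the authors' normalized table plus 0.5 with limma, protein-coding genes, the replicate number as a block, and each library left out in turn. The block keeps only replicate numbers present in both groups, so it uses the same libraries as the setting without double knockout replicate 3. The edgeR step was tested on simulated data: counts for the 12968 genes in this 2 against 3 design, 5 simulations, 250 changed genes per fold size. The changed genes were drawn from those with a mean of at least 10 CPM. With the observed dispersion it called 0.4% of genes changed 2-fold, 1.6% of those changed 4-fold, 10% of those changed 8-fold and 32.8% of those changed 16-fold, and 11 of its 123 calls were false. With that dispersion divided by 10 it called 37.6%, 88.8%, 96% and 98.8%. Camera called 5 of 5 lists with every gene raised 4-fold and 0 of 95 unshifted lists, for genes simulated as independent. Smaller shifts of a list were not simulated.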

Results

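Messenger RNA was measured in aortic cells, labelled vascular smooth muscle cells, from C57BL/6 mice aged 26 weeks. The comparison was between mice lacking ApoE, the lipoprotein ligand whose loss raises plasma cholesterol and leads to atherosclerosis, and mice lacking both ApoE and Neil3, a DNA glycosylase of base excision repair. It asks how loss of Neil3 alters the transcriptome of these cells. There were 2 libraries labelled ApoE knockout and 3 labelled double knockout. Depth went with genotype: the estimated counts totalled 730632 and 1549748 in ApoE knockout replicates 1 and 2, and 6813649, 3925916 and 4911964 in the libraries labelled double knockout. Genes with at least 10 counts numbered 7783 and 10873 in the former and 13073, 11982 and 12408 in the latter.

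The libraries also differed in transcripts of other tissues. Haemoglobin genes took 13.8% and 0.862% of the counts in ApoE knockout replicates 1 and 2, against 43.7%, 38.5% and 41.8% in the libraries labelled double knockout. Major urinary protein (Mup) genes, which are liver products, took 5.50% in ApoE knockout replicate 2, 1.19% in double knockout replicate 3 and at most 0.0903% in the other 3 libraries. The 28S ribosomal RNA gene Rn28s1 took 4.99% and 2.43% in the ApoE knockout libraries and between 0.305% and 1.27% in the others. Macrophage genes summed to 10738 and 20923 CPM of library totals in the ApoE knockout libraries and to 8207, 10576 and 14918 CPM in the others, while contractile smooth muscle genes summed to 4776 and 6211 CPM against 4638, 2123 and 3164 CPM. On library totals the larger haemoglobin share lowers both of these sums in the libraries labelled double knockout. Xist was present in every library, at 221 to 438 CPM. The Y-linked gene Ddx3y had 37 counts in ApoE knockout replicate 2, 22 in double knockout replicate 3 and 0 in the other 3, and Eif2s3y had 7, 3 and 0. Uty, also Y-linked, had 0 and 8 counts in ApoE knockout replicates 1 and 2 and 22, 18 and 13 in double knockout replicates 1 to 3, and Kdm5d had 0 in all.

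**Figure D1:**
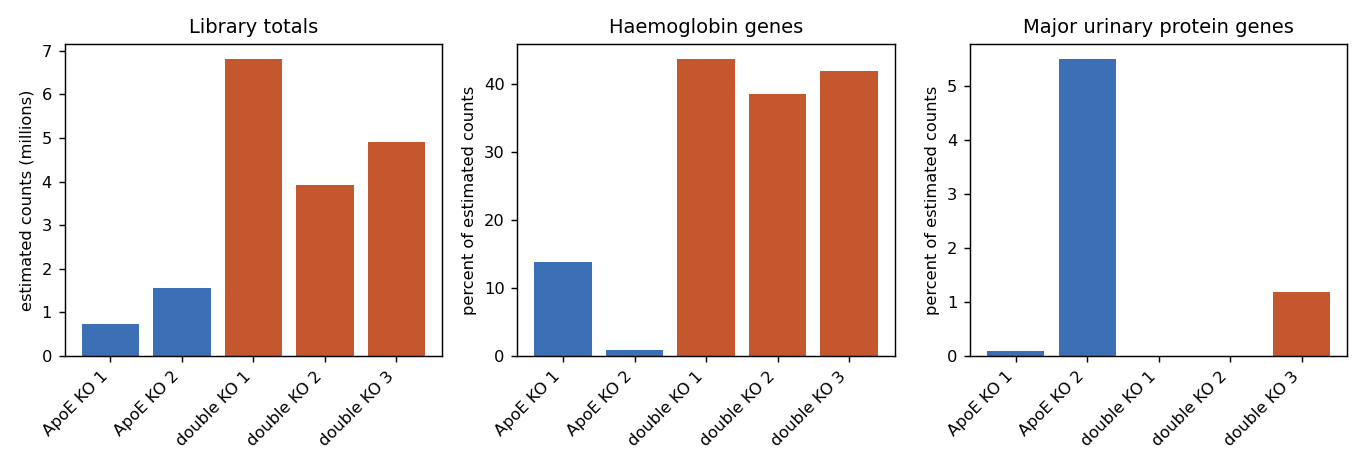
Estimated counts per library (left, axis in units of 1e+06), and the percent of them in haemoglobin genes (middle) and in major urinary protein genes (right); each bar is 1 library, blue for ApoE knockout and orange for double knockout as labelled. The libraries labelled double knockout are deeper and hold 38.5% to 43.7% haemoglobin counts, and major urinary protein counts are highest in ApoE knockout replicate 2, at 5.50%.

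Neil3 (chromosome 8, 53586867 to 53639065, GRCm38.p6) was higher in the libraries labelled as lacking it. It had 0 and 7 counts in the ApoE knockout libraries and 140, 61 and 131 counts in the libraries labelled double knockout. Normalised values were 1.66 ± 2.35 CPM (SD, n = 2) and 26.2 ± 6.47 CPM (SD, n = 3), a log2 fold change of 3.73 (SE 1.17, 95% interval 1.01 to 6.46) that did not pass the threshold (adjusted p = 0.748, edgeR). Without ApoE knockout replicate 2, whose 7 counts are all those of its group, the adjusted p was 0.0308 in edgeR, the lowest over 18 alternatives, which reached 0.9999. That value rests on a lone ApoE knockout library at 0 counts, assumed to vary like the 3 labelled double knockout. All Neil3 counts were assigned to a single transcript over its whole length, so they do not show whether reads lie in the deleted part of the gene, and as such they check nothing about the deletion. Every direction given here follows the labels, which these counts neither support nor exclude. Apoe, disrupted in both groups, had 209 and 141 counts in the ApoE knockout libraries and 224, 177 and 292 in the others, with a log2 fold change of -1.37 (SE 0.535, adjusted p = 0.748, edgeR), or -0.22 (adjusted p = 0.885) without ApoE knockout replicate 1 and -1.98 (adjusted p = 0.0346) without ApoE knockout replicate 2, each with a lone ApoE knockout library as above.

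No gene passed an adjusted p of 0.05 in edgeR: 0 were higher and 0 lower among 12968 tested, and the smallest adjusted p was 0.117. At an unadjusted p under 0.05 there were 644 higher and 190 lower genes, 834 in all where 648 are expected by chance; other splits of the 5 libraries gave 85 to 849, the highest with ApoE knockout replicate 2 and double knockout replicate 3 against the rest. DESeq2, run on 19223 genes without that expression filter, called 70 higher and 24 lower genes, 44 of these 94 with 0 counts in both ApoE knockout libraries, and limma-voom called Col2a1 higher and Erdr1, a gene named after its values were seen, lower. The groups did not overlap for 2393 genes in the upward and 1038 in the downward direction, 26.5% of all genes where chance gives 20%. Of the genes tested, 539 were at 0 in both ApoE knockout libraries and 13 in all those labelled double knockout. Depth went with genotype, so the excess of upward over downward genes in these counts cannot be told apart from depth. With an ApoE knockout library left out, all spread comes from the libraries labelled double knockout and the lone remaining library is assumed to vary like them, although the 2 differed widely (r = 0.567). On that assumption edgeR called 47 higher and 0 lower genes without ApoE knockout replicate 1, and 985 higher and 123 lower without ApoE knockout replicate 2. Of 60 named genes, the log2 fold change moved by over 1.5 times in 28 without the former and in 14 without the latter, and reversed in 0; 10 and 23 of them passed the threshold. The median log2 fold change of all genes was 0.21, against -0.55 on library totals and -0.84 on the TPM scale, so directions are relative to that median.

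In the upward direction, Col11a1, a cartilage collagen, was at 0 in both ApoE knockout libraries and at 147 ± 42.9 CPM (SD, n = 3) in those labelled double knockout, at least 148-fold higher (adjusted p = 0.117, edgeR). Clec3a, a cartilage lectin, was at least 275-fold higher (adjusted p = 0.185, edgeR) and the splicing regulator Sfswap at least 49.5-fold higher (adjusted p = 0.198, edgeR). Omd, which encodes a bone matrix proteoglycan, had 2 against 684 counts, a ratio of 83.6 with a counting interval of 23.1 to 692 (adjusted p = 0.248, edgeR). Hapln1, the cartilage link protein, had 5.34 ± 0.171 against 69.0 ± 15.7 CPM, with a log2 fold change of 3.68 (SE 0.530, adjusted p = 0.296, edgeR). In the downward direction stood Chchd10, a mitochondrial protein, Tmem170, Car3, a carbonic anhydrase abundant in fat and muscle, and the signal recognition particle RNAs Rn7s1 and Rn7s2, with log2 fold changes of -2.73, -2.57, -2.24 and -2.08 (the last for both RNAs, whose reads are shared) and adjusted p = 0.748 each in edgeR.

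**Figure D2:**
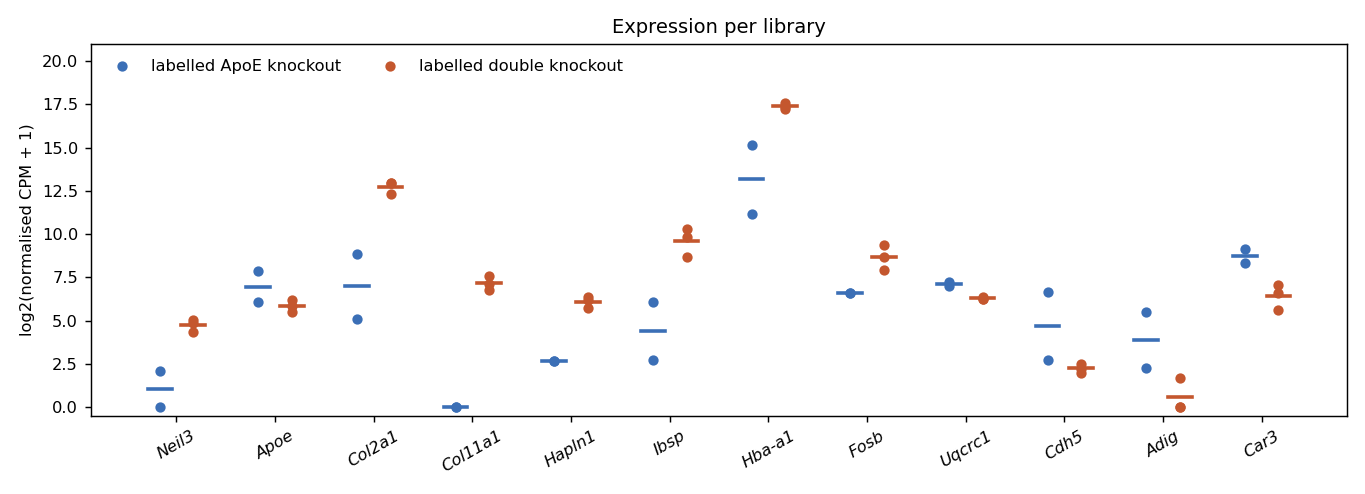
Normalised expression of 12 named genes on a log2(CPM + 1) axis; each point is 1 library, blue for ApoE knockout (n = 2) and orange for double knockout (n = 3) as labelled, and each line is the group mean. Neil3, at 0 and 3.32 CPM in the libraries labelled ApoE knockout, was at 19.2 to 31.8 CPM in those labelled double knockout.

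Of the 29 lists tested with camera, 6 were higher and 3 lower in the libraries labelled double knockout. None kept its call with an estimated correlation (adjusted p = 0.793 for each of the 9) or with fry. The estimated correlations of these 9 lists ranged from 0.196 for modulated smooth muscle to 0.637 for class II antigen presentation. The camera p values at the preset 0.01 thus assume far less dependence between genes than was estimated. No member of any list passed the threshold over all genes tested. Depth and the haemoglobin share (0.862% and 13.8% against 38.5% to 43.7%) moved with genotype for every list below.

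The osteochondrogenic list, genes of cartilage and bone formation, was higher. All 18 measured members had fitted values above 0, 8 passed when adjusted over the list alone, and the median log2 fold change was 3.36, or 3.07 with genes at 0 set to their bound (camera adjusted p = 1.71e-15; adjusted p = 0.793 with an estimated correlation). The median was 6.65 without ApoE knockout replicate 1 and 2.17 without double knockout replicate 2. In the former, 6 of 19 measured members have 0 counts in the remaining ApoE knockout library, and fits against 0 are no bounds. Col2a1, the main collagen of cartilage, had 251 ± 308 CPM (SD, n = 2) against 7035 ± 1709 CPM (SD, n = 3), a log2 fold change of 4.81 (SE 1.14). Ibsp, or bone sialoprotein, had a log2 fold change of 4.63 and Alpl, the alkaline phosphatase of mineralisation, one of 3.53.

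Erythroid and platelet genes were higher too: 8 of 10 measured members passed when adjusted over the list alone, with a median of 3.07, or 2.86 bounded (camera adjusted p = 1.32e-09; adjusted p = 0.793 with an estimated correlation). The median was 6.26 without ApoE knockout replicate 1 and 2.30 without ApoE knockout replicate 2. Slc4a1, the anion exchanger of the red cell membrane, had a log2 fold change of 2.37, and the globin genes Hbb-bt and Hba-a1 had 3.49 and 3.17.

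Immediate early and dissociation stress genes, which respond within minutes to cell handling, all had fitted values above 0 (25 of 25; 0 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 6.82e-09; adjusted p = 0.793 with an estimated correlation). Fosb had 94.2 ± 0.355 CPM (SD, n = 2) against 436 ± 210 CPM (SD, n = 3); Btg2, Fos and Ccn1 had log2 fold changes of 1.30, 1.18 and 2.51. On the TPM scale the list's median was -0.27, above that scale's median of all genes of -0.84.

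Inflammatory cytokine and NF-kB target genes had a median of 0.95 over 23 genes (1 adjusted over the list alone; camera adjusted p = 0.00765; adjusted p = 0.793 with an estimated correlation). That gene was Ptgs2, the inducible cyclooxygenase, with 2 against 635 counts, a ratio of 77.6 with a counting interval of 21.4 to 643. Il1rl1 was at least 6.76-fold higher, and Csf1 and Icam1 had log2 fold changes of 1.77 and 0.90. The call was lost without ApoE knockout replicate 2 (camera adjusted p = 0.330, with a median of 1.21) and without double knockout replicate 1 (camera adjusted p = 0.236, with a median of 0.38).

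Modulated smooth muscle genes, markers of smooth muscle cells that have left the contractile state, had a median of 0.83 over 22 genes (1 adjusted over the list alone; camera adjusted p = 0.0378; adjusted p = 0.793 with an estimated correlation). The passing member was Tnfrsf11b, which encodes osteoprotegerin, an inhibitor of bone resorption, with a log2 fold change of 5.23 (SE 1.04); Fn1, Ecrg4 and Tpm4 had 1.38, 2.42 and 0.88. Class II antigen presentation genes had a median of 0.41 over 9 genes (0 adjusted over the list alone, camera adjusted p = 0.0191, and adjusted p = 0.793 with an estimated correlation). The list was led by H2-DMb1 at 1.30, with Ciita and H2-Ob at 2.68 and 1.14. H2-Oa was at least 6.16-fold higher on average but at 1.70 CPM in double knockout replicate 3. Without ApoE knockout replicate 2 camera gave adjusted p = 0.138 for the former list and, in the opposite direction, 0.768 for the latter. Without double knockout replicate 1 the values were 0.228 and 0.236, and without double knockout replicate 2 the modulated list had 0.0545. The modulated median was 0.92 without ApoE knockout replicate 2, and 0.44 and 0.73 without double knockout replicates 1 and 2; the class II median was 1.36 and -0.10 without ApoE knockout replicates 1 and 2, and 0.13 and 0.62 without double knockout replicates 1 and 3. On library totals the adjusted p values were 0.247 and 0.160, with medians of 0.06 and -0.32, and the class II list had 0.256, with a median of 0.24, after thinning all libraries to the smallest total, haemoglobin included. The medians of the inflammatory, modulated and class II lists were -0.38, -0.55 and -0.64 on the TPM scale.

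Oxidative phosphorylation genes were lower, with 29 of 33 fitted values below 0, none passing when adjusted over the list alone and a median of -0.49 (camera adjusted p = 7.52e-06; adjusted p = 0.793 with an estimated correlation). Uqcrc1, a subunit of respiratory complex III, had 137 ± 14.1 CPM (SD, n = 2) against 77.2 ± 3.55 CPM (SD, n = 3), and Uqcrc2, Sdha and Uqcrfs1 had log2 fold changes of -1.11, -0.98 and -0.92. Adipocyte genes had a median of -1.66 over 17 genes (0 adjusted over the list alone; camera adjusted p = 0.00104; adjusted p = 0.793 with an estimated correlation), with Scd1, Pparg and Adig at -1.70, -1.81 and -5.06, and Cidec, in the other direction, at least 11.7-fold higher. Endothelial genes had a median of -1.10 over 14 genes (0 adjusted over the list alone; camera adjusted p = 0.0383; adjusted p = 0.793 with an estimated correlation), with Vwf, Cdh5, Fabp4 and Eng at -2.74, -3.79, -2.31 and -0.83. These 3 lists rested on ApoE knockout replicate 1, where adipocyte genes summed to 7202 CPM of library totals and endothelial genes to 2287 CPM, against 3546 and 451 CPM in replicate 2. Without it camera called none of these 3 lists, and it pointed upward for adipocyte and endothelial genes. The medians for oxidative phosphorylation, adipocyte and endothelial genes were -0.11, 1.01 and 1.19. Vwf, Cdh5, Fabp4 and Eng were still below 0 there, at -1.24, -0.58, -0.26 and -0.49. So were Scd1, Pparg and Adig, at -0.52, -0.12 and -2.36. The medians above 0 therefore come from other members, among them Cidec, a fit against 0 that is no bound. The adipocyte median was -2.32 without ApoE knockout replicate 2. Without double knockout replicate 3 the endothelial list had adjusted p = 0.113 and a median of -1.23. It was also not called with RLE normalization (0.0582, median -1.19), library totals (0.247, median -1.82) and no expression filter (0.46, median -0.63), so that the median was nearer 0 only in the last of these 4 settings.

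**Figure D3:**
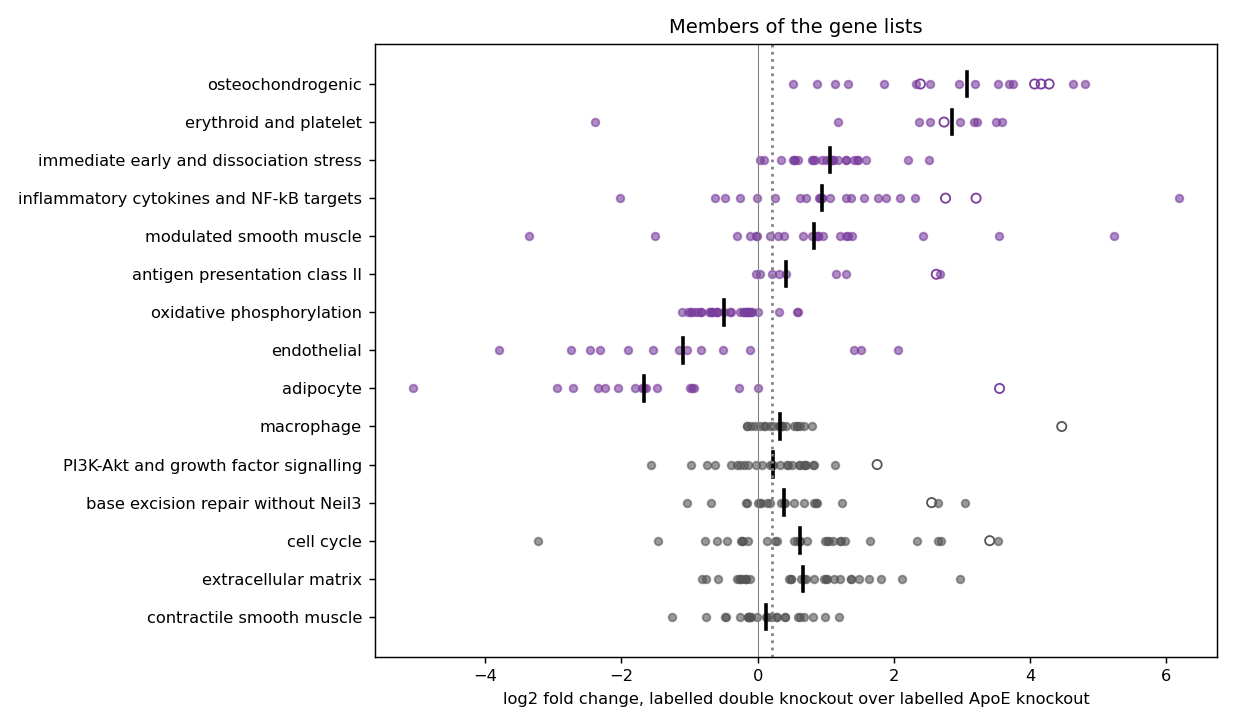
Log2 fold change of each measured member of 15 gene lists, labelled double knockout over labelled ApoE knockout; purple lists were called by camera, grey lists were not. Open circles are genes at 0 in a whole group, drawn at their bound, black lines are medians, and the dotted line is the median of all genes (0.21).

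The other 20 lists tested were not called with all 5 libraries and the settings chosen in advance as the main ones. Contractile smooth muscle genes had a median of 0.12 over 25 genes, while camera pointed downward (adjusted p = 0.548), and Lmod1 and Mylk had log2 fold changes of 0.81 and 0.59. Extracellular matrix genes had a median of 0.66 (camera adjusted p = 0.108), with the matrix glycoprotein Sparc at 2.13 and Col5a2 at 1.81. Base excision repair genes other than Neil3 had a median of 0.38 (camera adjusted p = 0.397); Mbd4 was at least 5.87-fold higher and Aptx had a log2 fold change of 2.65. Cell cycle genes had a median of 0.62 (camera adjusted p = 0.318), with Bub1b at 3.53. Ccnb2 was at least 10.6-fold higher on average but at 1.38 CPM in double knockout replicate 1. Macrophage genes had a median of 0.33 (camera adjusted p = 0.172), with Ptprc at 0.80 and Lyve1 at least 22.1-fold higher on average but at 0 in double knockout replicate 3. Growth factor and PI3K-Akt genes had a median of 0.22 (camera adjusted p = 0.987), with Gsk3b at -0.97. Pik3ca was at least 3.37-fold higher on average but at 1.22 CPM in double knockout replicate 3. None of these 6 lists had a member passing when adjusted over the list alone. Over the left-out libraries their medians ranged from -0.30 to 0.36 for contractile, 0.13 to 0.97 for matrix, 0.02 to 0.70 for repair, 0.25 to 5.78 for cell cycle, 0.10 to 0.83 for macrophage and 0.04 to 0.14 for growth factor genes; the 5.78 is without ApoE knockout replicate 2, where 16 of 31 cell cycle genes have 0 counts in the remaining ApoE knockout library. Camera with the preset correlation called matrix genes higher without double knockout replicate 3 (adjusted p = 1.52e-05) and with the replicate number as a block (0.000135), which leaves out that library too. It also called them higher with no expression filter (0.0110). Without ApoE knockout replicate 1 it called them higher too, with a median of 0.82, but that fit rests on a lone ApoE knockout library. It called macrophage genes higher without ApoE knockout replicate 2 (0.00201) and contractile genes lower without double knockout replicate 1 (0.0313).

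Camera adjusted p was 0.108 for TGF-beta and BMP signalling, 0.117 for Schwann and neuronal, 0.259 for interferon response, 0.291 for unfolded protein response, 0.311 for adventitial fibroblast, and 0.318 for both Notch signalling and cholesterol efflux. It was 0.484 for p53 targets, 0.499 for Nrf2 and antioxidant, 0.569 for neutrophil and mast cell, 0.575 for lymphocyte, 0.609 for cholesterol synthesis, 0.716 for mural pericyte and 0.896 for cardiac and skeletal muscle genes. No member of these 14 lists passed when adjusted over the list alone. Some were called in other settings: TGF-beta and BMP genes higher without ApoE knockout replicate 1 (0.00496), without double knockout replicate 3 (0.0197) and with no expression filter (0.0271), unfolded protein response genes higher without ApoE knockout replicate 2 (0.00875), and adventitial fibroblast genes higher without double knockout replicate 3 (2.24e-06) and with the block (4.14e-05). Schwann and neuronal genes were called lower without ApoE knockout replicate 1 (0.0225) and without double knockout replicates 1 (0.0313) and 2 (0.0406), cholesterol efflux genes lower without double knockout replicates 2 (0.0406) and 3 (0.0222) and on library totals (0.0175), and Nrf2 genes lower on library totals (0.0433). For Nrf2 and cholesterol synthesis genes the median was above 0 and camera pointed downward, and for pericyte genes the reverse held. Cholesterol efflux genes had a median of -0.16 and a mean of 0.35. Only 3 mesothelial and epithelial genes were measured, too few to test.

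Replicates of a group differed widely. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.567 between the ApoE knockout libraries, 0.764 to 0.879 among those labelled double knockout and 0.589 to 0.756 between the groups. No libraries held identical values. The first principal component, with 55.5% of the variance, separated ApoE knockout replicate 1 from the other 4 libraries, and the common biological coefficient of variation was 0.741.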

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

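The tests on Neil3 below were chosen after its values had been seen. Among transcripts that matched no gene, which the gene comparison does not use, 362 had enough counts to test and 3 passed in edgeR when adjusted among themselves. These were XM_006521271.1 (0, 0, 533, 308 and 214 counts in ApoE knockout replicates 1 and 2 and double knockout replicates 1 to 3), XM_017319953.2 (0, 0, 376, 194 and 769) and XM_006527417.1 (0, 0, 208, 94 and 119), with adjusted p from 0.0167 to 0.0433. Adjusted together with all genes, their p ranged from 0.192 to 0.368. Their genes were not identified here.

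Neil3 was higher in the libraries labelled as lacking it. Fewer reads in the ApoE knockout libraries are argued against: their pooled 7 counts allow at most 6.56 CPM (95% Poisson limit), below the lowest library labelled double knockout at 15.8 CPM. More dividing cells were not shown: the cell cycle list had a median log2 fold change of 0.622 (95% bootstrap interval 0.192 to 1.08), and 0.21 for all genes lies inside that interval. Its genes summed to 357 and 697 CPM of library totals in the ApoE knockout libraries and to 367, 327 and 626 CPM in the others. On that scale the larger haemoglobin share lowers other genes in the libraries labelled double knockout, so these sums do not weigh against dividing cells. The interval of the median also reaches past the lower limit for Neil3 of 1.01, so a contribution of dividing cells cannot be told apart. Leaving out 1 library moved both: the cell cycle median was 0.25 without double knockout replicate 3 and 5.78 without ApoE knockout replicate 2, and the limit for Neil3 was -0.27 and 5.48 there, and -0.12 and 0.32 without double knockout replicates 1 and 2; without ApoE knockout replicate 1 the cell cycle median was 0.33 (-0.06 to 0.78), below the limit for Neil3 of 1.26 there, which goes against dividing cells as the whole cause but rests on a lone ApoE knockout library. Exchanged genotype labels stay open because 0 genes other than Neil3 differ between the genotypes by design, and reads outside the deleted part stay open because the 1 Neil3 transcript with counts has a single value over its whole length. A response of the Neil3 locus to the knockout itself was not tested.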

How the results depend on the processing

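Thinning reads, leaving out haemoglobin, Mup and structural RNA genes, and testing lists on library totals were added after the data had been seen. Genes called higher and lower, 0 and 0 in edgeR, became 16 and 4 without the expression filter and 70 and 24 with DESeq2. Both ran on 19223 genes, but DESeq2 gave 6742 of them no adjusted p. Tool and genes adjusted over therefore changed together against the 12968 genes of edgeR. The calls were 1 and 1 with limma-voom, and 3 and 7 with the replicate number as a block, which leaves out double knockout replicate 3. The numbers do not pair the mice (correlation of same-numbered differences 0.0106), and the same 4 libraries without the block gave 0 and 0. RLE, library totals, a mean of 1 CPM, length offsets, TPM, the authors' table, protein-coding genes, thinning and leaving out haemoglobin and the like gave 0 and 0. Leaving out each library gave 0 to 985 higher and 0 to 123 lower genes; where this leaves a lone ApoE knockout library, it is assumed to vary like the other group. The cause of these moves was not tested.

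Lists called higher and lower, 6 and 3 with camera, became 0 and 0 with an estimated correlation and 0 and 0 with fry, and ranged from 3 to 9 and from 1 to 5 over the left-out libraries. The Neil3 log2 fold change was above 0 in all 18 alternatives, from 2.99 to 9.45 over the left-out libraries; the highest is a fit against a library at 0 and is no bound. With the block it was 4.04.

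Single genes reversed 10 times, never past the threshold. On the TPM scale, where the median shift per gene was -1.17, the log2 fold change was -0.47 for Lmod1, -0.74 for Mylk, -0.44 for Tpm4, -0.39 for Icam1, -0.062 for H2-DMb1, -0.085 for Btg2, -0.12 for Fos and -0.52 for Ptprc. Mylk was -0.17 on library totals, and Gsk3b was 2.94 in the authors' table, where the cause was not tested. Dispersion limits what can be called: simulated 8-fold changes were called in 10% of cases with the observed dispersion and in 96% with that dispersion divided by 10. Depth was not varied there.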

Other observations

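The tests of haemoglobin and of bone marrow, and the hepatocyte, erythroid precursor, granulocyte and further cartilage lists, were chosen after the data had been seen. The other tests below were set down before their results. Liver genes were high in ApoE knockout replicate 2 and double knockout replicate 3. A hepatocyte list of 18 genes summed to 22661 and 4902 CPM of library totals in these, against 1462, 262 and 305 CPM in ApoE knockout replicate 1 and double knockout replicates 1 and 2. Alb, the plasma albumin gene, had 4690 and 972 CPM there and 373, 15.5 and 13.2 CPM in the others. The median log2 fold change of the list between genotypes was -2.19, and 0 of its genes had an unadjusted p under 0.05. The erythroid precursor list had a median of 1.74 over 11 genes.

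Erdr1 (chromosome X), named after its values were seen and annotated as a transcribed pseudogene, had 1945 and 1698 CPM in the ApoE knockout libraries against 40.1, 8.17 and 41.3 CPM. Its log2 fold change was -5.92 (SE 0.733, adjusted p = 0.188, edgeR), and the adjusted p was 1.18e-14 in DESeq2 and 0.00102 in limma-voom, with a range up to 0.9999 over the alternatives, reached without double knockout replicate 1. The log2 fold change was -6.22 there, and it ranged from -6.27 to -5.51 over the left-out libraries.

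Cartilage and bone genes were higher in the libraries labelled double knockout, and a candidate explanation is cartilage cells. The 16 measured genes of another cartilage list share none with the osteochondrogenic list. None of these genes passed when adjusted over the list alone, and 5 had an unadjusted p under 0.05. Their median log2 fold change was 2.28 (lower 95% bootstrap limit 1.08) against 0.21 for all genes. It was 6.24 without ApoE knockout replicate 1, where 10 of 18 genes have 0 counts in the remaining ApoE knockout library. Cartilage genes taken on by smooth muscle cells would raise this list too, so it does not separate these explanations. Of the 18 genes on that list 15 also had counts in an ApoE knockout library, and Col11a2 was at 425, 514 and 209 CPM of library totals against 92.8 and 0. Haemoglobin taking a share of the counts is argued against as the source of the rise. On library totals its larger share can only lower other genes in the libraries labelled double knockout, so the check bears on the scaling alone. The osteochondrogenic list still had a median log2 fold change of 2.64 there (95% bootstrap interval over genes 1.39 to 4.01), or 1.45 (0.086 to 2.83) without double knockout replicate 2. It was 5.91 without ApoE knockout replicate 1, where 6 of 19 genes have 0 counts in the remaining ApoE knockout library. Bone marrow carried over with bone cannot be told apart, because 9 granulocyte genes had a median of 1.53 with a wide interval (-0.28 to 5.53) around the 1.68 set as the bound. It was 6.29 and 0.66 without ApoE knockout replicate 2 and double knockout replicate 1. In the former fit, 8 of 11 genes have 0 counts in the remaining ApoE knockout library. Smooth muscle cells of this genotype taking on cartilage genes was not tested, and which fraction of the CD31 and CD90.1 bead selection was kept is not given in the sources used here.

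ApoE knockout replicate 1 had few detected genes. Lower depth is argued against as the whole cause: libraries labelled double knockout thinned to its 599367 counts outside haemoglobin detected at least 13811 genes in each of 20 draws, against 10077 in that library.

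A stretch of the donor strain around Neil3 might carry other differences. Of 191 genes within 20 Mb, 10 had an unadjusted p under 0.05. That is 5.24%, against 6.45% of other genes (one-sided Fisher's exact p = 0.792). The odds ratio was 0.801 (95% interval 0.376 to 1.52), with its upper limit below the bound of 2 set beforehand. Such genes were thus not much more frequent near Neil3. How often strain differences would reach an unadjusted p under 0.05 was not simulated, and simulated 4-fold changes passed the adjusted threshold in 1.6% of cases. The count therefore cannot exclude such differences. The odds ratio was 0.237 (upper limit 1.35) and 0.496 (1.84) without double knockout replicates 1 and 2. Without double knockout replicate 3 its interval was 0.494 to 2.00, which reaches that bound, so the result depends on that library.

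With 5 libraries there are 10 splits of 2 against 3, too few for a share under 0.05. The real split called 0 genes, which 10 of 10 splits must reach, so that count says nothing, and the highest other called 36. For lists, 8 of 10 splits called as many as the real 9, and the highest other called 17. Both highest values came from grouping ApoE knockout replicate 2 with double knockout replicate 3, which points to a structure of the samples that crosses genotype, along with the liver genes high in both.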
